A study of Mus musculus with 5 samples.

How the data were processed

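The series measured RNA of adherent peritoneal macrophages from 8 week old mice with 1-colour Agilent arrays. Cells were taken by peritoneal lavage and plated overnight, floating cells were then removed, and the remaining cells gave the RNA, per the labels' design text. Total RNA was purified on columns and 50 ng of it was turned into Cy3-labelled cRNA with the manufacturer's kit, per the labels' protocols. The mice were kept on a mixed strain background, wild-type animals were littermates, and either sex was used, per the labels. Sex-linked transcripts marked wild-type 11 as male and the other arrays as female, so sex was not balanced between the groups. There were 3 wild-type arrays, numbered 5, 11 and 14 in the sample titles, and 2 arrays of c-Jun-deleted mice, numbered 1 and 9. Groups were taken from the titles and genotypes, which give floxed c-Jun alleles with LysM-Cre for the c-Jun-deleted samples, whereas their source names and the header of the authors' deposited table name another Cre line, Mx. The source names speak of numbered mice, so the samples were treated as separate animals; if they were not, the p-values measure only the spread between these samples. The number of arrays limits the precision of every value.

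The authors' scanner files hold the intensity of each spot as Feature Extraction 11.5.1.1 wrote it, per the file headers. The processed signal in them is background-subtracted, and the brightest spots were taken from a weaker scan and scaled up, with no scaling between arrays. The deposited scanner files also hold 0 or 1 flags for spots well above background, saturated or outlying, an other kind of value used only for filtering. The deposited series table holds log2 values after a 75th percentile shift, per its file name, as 1 mean per group with no single arrays. Medians of its wild-type and c-Jun-deleted columns were 0.54 and 1.19. The baseline that was subtracted from each probe there stays unknown, so only the difference between its columns was used. Its scale was found from the scanner files: for 1692 of 1709 probes the column difference lay within 0.001 of the difference computed here, and the largest gap was 0.17. Its header names 4 wild-type arrays, of which 1 is not used here. The match was reached with wild-type 5, 11 and 14 alone and with flagged spots kept, so the column matches a mean without that array.

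Each array had 62976 spots, 59305 of them not controls, for 55681 distinct probes. The 75th percentile of the processed signal over non-control spots was 474 on wild-type 5, 456 on wild-type 11, 482 on wild-type 14, 596 on c-Jun-deleted 1 and 437 on c-Jun-deleted 9. Log2 of the signal minus log2 of that percentile was the main value. Control spots and spots with an outlier flag were left out, and the spots of 1 probe were averaged, which concerned 432 probes. Probes well above background on at least 2 of the 5 arrays were kept (32821), and 256 of these dropped out because a flagged spot left an array without a value. No probe was saturated.

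Probes were named by matching the transcript accession in the files, without version, to a table of gene symbols of assembly GRCm38.p6. The arrays were designed on mm9, so no coordinates are given and that table served only for names and for which genes lie near each other. A symbol was found for 28026 probes (21154 symbols), and 27655 probes stayed unnamed. A named gene was its brightest probe by the mean over all arrays, and unnamed probes entered the test as they were, for 27938 genes tested, 14641 of them with a symbol. Among 3843 symbols with several tested probes, 5 had probes of opposite sign at unadjusted p below 0.05.

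Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariate), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Differences are c-Jun-deleted minus wild-type in log2, with the fit's standard error (SE). An exact permutation test of 3 against 2 arrays cannot give a p below 0.1, so none was run. Gene lists were tested with limma's camera, each list against all other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 23 lists with at least 3 measured genes. Camera with the correlation estimated from the residuals, and fry, were run beside it. A gene that was not well above background on any array of a group has only a bound there: its fold is given as at least the bright group's mean over the dim group's mean of the higher of its own signal and the lowest signal well above background on each array.

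The files hold 2 slides, and scanning time coincides with them. Slide 1 carried wild-type 5 and c-Jun-deleted 1, and slide 2 carried wild-type 11, wild-type 14 and c-Jun-deleted 9. Values with the slide as a block and within each slide are therefore given. The 24 gene lists (1 of them, sex-linked genes, had fewer than 3 measured members and was not tested), the rule for named genes, the tests and all but 2 of the alternatives were fixed before the data were examined. Named are Jun, Ptgs2, Arg1, Lyz2 and Lyz1; the 12 genes with the largest rise and the 12 with the largest fall past the threshold, with places left over filled by the smallest unadjusted p among genes with at least a 2-fold difference and no overlap between groups; and up to 4 members of each described list with the smallest unadjusted p, or any member of the AP-1 list. Genes outside this rule are said to be so.

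The fit was tested on simulated data with the means of the 27938 genes and the variance prior of this comparison. In 200 genes changed in the c-Jun-deleted arrays, it called 0 of 67 changes of 1 in log2, 17 of 67 changes of 2 and 49 of 66 changes of 4, with 4 false calls. Camera's p for a simulated list of 23 genes shifted by 1 in log2 was 3.57e-24, and 1 of 100 unchanged lists came below the threshold. The simulated genes were independent of each other.

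Alternatives were background correction by normexp with offset 50 followed by quantile normalization, quantile normalization, median centring, no filter or a filter on all 5 arrays, each probe on its own, the slide as a block and within slides, the number in the source names as replicate block, a trended and robust variance prior, array weights, flagged spots kept, other thresholds, and each array left out in turn. The files hold no mean spot signal, so normexp used the median spot signal, and the joint removal of wild-type 11 and c-Jun-deleted 1 was added, both chosen after seeing the data.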

Results

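RNA of peritoneal macrophages was measured on 1-colour arrays in 3 wild-type mice (numbers 5, 11 and 14) and 2 mice with c-Jun deleted in myeloid cells (numbers 1 and 9). The c-Jun-deleted mice carry floxed Jun alleles and LysM-Cre, a recombinase placed in the Lyz2 gene, per the titles; their source names give another Cre line, Mx. Between 52.1% and 59.9% of the probes were well above background on an array. Pearson's r across genes between arrays ranged from 0.955 (wild-type 14 and c-Jun-deleted 9) to 0.984 (both c-Jun-deleted arrays); genes are not independent replicates. The first principal component, with 44.4% of the variance, placed the c-Jun-deleted arrays at 44.2 and 87.2 and the wild-type arrays at -38.5, -15.8 and -77.2. On the second, with 29.6%, wild-type 5, 11 and 14 lay at 5.85, -91.7 and 44.95 and c-Jun-deleted 1 and 9 at 30.7 and 10.2. Values are log2 of the signal relative to each array's 75th percentile.

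The first question was how Jun, Ptgs2, Arg1 and Lyz2, which were fixed beforehand, differed between the genotypes. Jun, the AP-1 subunit that was targeted, was at 3.21, 3.75 and 3.17 in wild-type and at 2.76 and 2.71 in c-Jun-deleted macrophages, 1.56-fold lower (log2 difference -0.64, SE 0.23), and still well above background on every array. Ptgs2, which encodes the prostaglandin synthase Cox-2, was 2.47-fold lower (-1.30, SE 0.50), with 0.15, 0.03 and 1.11 in wild-type and -0.29 and -1.46 in c-Jun-deleted macrophages. Arg1, which encodes arginase 1, was at 5.73, 3.70 and 5.93 against 5.52 and 4.12 (-0.30, SE 0.85), so the groups overlapped. Lyz2, the lysozyme gene that carries LysM-Cre, was at 8.70, 8.76 and 9.18 in wild-type, at 4.46 in c-Jun-deleted 1 and at 8.52 in c-Jun-deleted 9, which is 21.4-fold and 1.29-fold below the wild-type mean. None of these differences passed the limma test over all genes (Benjamini-Hochberg adjusted p = 0.391 for Jun, 0.412 for Ptgs2, 0.902 for Arg1 and 0.479 for Lyz2). With the slide as a block the differences were -0.62, -1.35, -0.49 and -2.07, in the same order. Within slide 1 they were -0.45, -0.44, -0.21 and -4.24, and within slide 2, which holds a single c-Jun-deleted array, they were -0.75, -2.03, -0.69 and -0.45. The Ptgs2 difference was -0.72 without c-Jun-deleted 9 and -1.88 without c-Jun-deleted 1, and that of Lyz2 was -4.42 and -0.36. The Arg1 difference was -1.01 without wild-type 11, -0.997 without c-Jun-deleted 1, 0.0043 without wild-type 5, 0.11 without wild-type 14 and 0.40 without c-Jun-deleted 9. Where the single Jun probe lies relative to the deleted part is not known here, so its level does not check the genotype. Lyz1, a near-identical copy of Lyz2, was at 7.59 ± 0.05 (SD, n = 3) in wild-type and 8.06 ± 0.17 (SD, n = 2) in c-Jun-deleted macrophages. An outlying Lyz1 spot on 1 array was kept, and no test was run. Lyz1 was highest, at 8.18, on c-Jun-deleted 1, where Lyz2 was lowest, so its signal did not follow that of Lyz2 there.

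**Figure D1:**
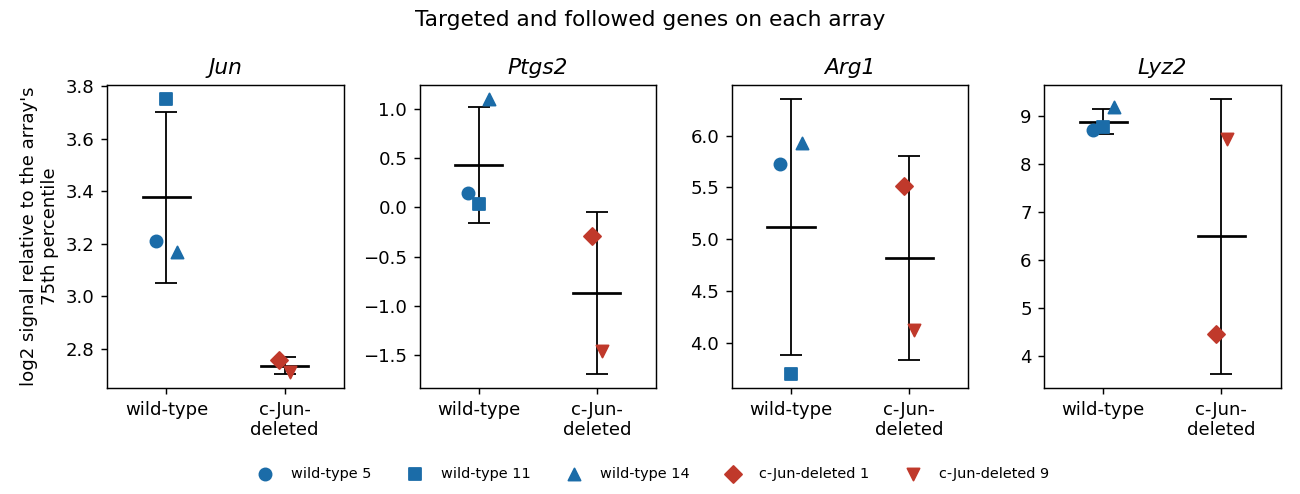
Log2 signal relative to the array's 75th percentile (y axis) of Jun, Ptgs2, Arg1 and Lyz2, with 1 marker per array, wild-type in blue and c-Jun-deleted in red, and the group mean ± SD in black. Both c-Jun-deleted arrays lie near 2.7 for Jun, and for Lyz2 only c-Jun-deleted 1, at 4.46, lies far from the other arrays.

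The next question was which genes differed over the whole array. The genes with the smallest p among those higher in c-Jun-deleted macrophages were Nkx6-3, a homeobox gene (at least 2.77-fold, not well above background on any wild-type array), and Snhg3, a small nucleolar RNA host gene (log2 difference 2.11, SE 0.15). Then came Pdzd2 (at least 3.41-fold), Dyrk4 (at least 2.01-fold), Ppl, which encodes periplakin (3.10), and Mall (3.40), both well above background on 2 of 3 wild-type arrays, then Smc1b, a cohesin gene (at least 1.78-fold), and the globin gene Hbb-b1 (at least 3.10-fold). The list was completed by 4833422C13Rik (2.11), Grb7 (2.37), Hoxb7 (1.68) and Aff3 (2.34). Lower in c-Jun-deleted macrophages were Sod3, the extracellular superoxide dismutase (-1.67, SE 0.14), Ankrd37 (-2.07) and Ptprf (-1.51). Also lower, but well above background on only 1 of 2 c-Jun-deleted arrays, so that the size is uncertain, were Mrap, an accessory protein of the melanocortin receptor (-2.40), Lilra5 (-2.42), Alms1 (-1.77) and 1700029H14Rik (-1.72). Not well above background on either c-Jun-deleted array, and lower there, were 1700024G13Rik (at least 4.90-fold), Olfr1052 (at least 2.52-fold), Npy1r (at least 2.16-fold), Ism1 (at least 2.23-fold) and Fbln7 (at least 1.40-fold). None of these 24 genes passed: limma's adjusted p was 0.0955 for Nkx6-3, 0.163 for Snhg3 and from 0.173 to 0.217 for the others. With normexp, which here also used the median spot signal and quantile normalization, the Nkx6-3 difference was -0.16. Under it Ppl was at 1.73, Mall at 1.70, Grb7 at 1.31, Hoxb7 at 0.75, Sod3 at -1.07, Mrap at -0.70, Lilra5 at -1.01, Ptprf at -0.74, Alms1 at -0.48 and 1700029H14Rik at -0.33. Of the genes given as bounds, normexp put Pdzd2 at 1.03, Dyrk4 at 0.60, Smc1b at 0.47 and Hbb-b1 at 0.81. It put 1700024G13Rik at -0.69, Olfr1052 at -0.41, Npy1r at -0.35, Ism1 at -0.20 and Fbln7 at -0.29. The bounds therefore do not hold under that setting, and no alternative varied its offset alone.

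Of 27938 genes tested with limma, 0 had an adjusted p below 0.05 and 1, Nkx6-3, lay below 0.1. At an unadjusted p below 0.05 there were 3395 genes, 1572 higher and 1823 lower in c-Jun-deleted macrophages, where 1397 would come by chance. The higher ones made up 46.3% of these, 61.2% with normexp, 62.0% with quantile normalization and 79.0% with median centring, under which 187 genes passed the adjusted threshold. The median difference over all genes was -0.09 and with median centring 0.12, so a direction of small differences depends on the scaling. With the slide as a block 0 genes passed and 2724 lay below an unadjusted 0.05, and within slide 2, with its single c-Jun-deleted array assumed to vary like the wild-type ones, these were 0 and 1836. Groups did not overlap for 9372 genes, 33.5% against 20% by chance, and 2280 of these differed at least 2-fold, 1086 higher and 1194 lower. Both chance figures are averages from which a single split of the arrays can lie far, because genes vary together. No other split was counted, so the excess cannot be credited to the genotype.

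B cell markers rose together in c-Jun-deleted macrophages, with all 23 measured genes higher and a median difference of 2.19, a 4.55-fold median (camera adjusted p = 1.04e-25, and 0.712 with an estimated correlation). Among them were Tnfrsf13c, a receptor for the B cell survival factor BAFF (2.09), Fcrla (2.76), Pou2af1, a B cell transcriptional coactivator (2.51), and Ly6d (2.51). Globin genes were higher as well, and the erythroid list rose with a median of 4.14 over 7 measured genes, or 3.52 with 2 of them at their bound (camera adjusted p = 1.68e-05, and 0.712 with an estimated correlation). That median was 1.69 with normexp and 2.44 without the filter on dim probes. Hba-a2 was at 4.14. Hbb-bt, well above background on 1 of 3 wild-type arrays, was at 4.87 and with normexp at 2.47, and Hbb-b2 was at least 11.4-fold higher, with a normexp difference of 1.69. All 5 higher genes of the erythroid list were globins. Its other 2 genes, Slc4a1 (-0.46) and Car1 (-0.06), chosen after their values were seen, were not higher. The list therefore shows a rise of globins and not of erythroid genes at large. MHC class II presentation genes rose by a median of 0.26 with 8 of 11 genes higher (camera adjusted p = 0.00259, and 0.712 with an estimated correlation), led by H2-Ob (2.46), H2-DMb2 (2.28), H2-Eb2 (2.17) and H2-Oa (2.00), beside the B cell median of 2.19. Adjusted over the list alone, 22 B cell, 5 erythroid and 4 MHC class II genes passed, and over all genes 0. With the slide as a block the medians were 2.17, 4.13 and 0.38, within slide 1 they were 1.69, 2.97 and 0.53, and within slide 2 they were 2.58, 5.01 and 0.27. These 3 lists passed camera with each wild-type array left out and with the block, always with the preset correlation of 0.01. The estimated correlations were 0.633, 0.334 and 0.546, so these passes do not show that the calls hold for correlated genes. On the MHC class II list, however, wild-type 11 stood at 0.59 relative to the wild-type mean, above c-Jun-deleted 1 (0.09) and c-Jun-deleted 9 (0.55), and wild-type 14 at -0.64. The median of that list was 1.15 without wild-type 11, -0.13 without wild-type 14, 0.07 without wild-type 5, 0.55 without c-Jun-deleted 1 and 0.09 without c-Jun-deleted 9. It was 0.66 with array weights, and 0.43, 0.40 and 0.47 under normexp, quantile normalization and median centring.

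Markers of large peritoneal macrophages, the resident macrophages of the cavity, rose by a median of 0.79, with 22 of 28 genes higher (camera adjusted p = 0.000311, and 0.712 with an estimated correlation). Examples are Itga6 (1.24), Cd93 (1.21), Bhlhe41 (1.84, and 1.21 with normexp) and Tgfb2 (2.53). T and NK cell markers rose by a median of 0.34 with 20 of 29 genes higher (camera adjusted p = 0.0206, and 0.773 with an estimated correlation), among them Cd2 (2.16) and Tcf7 (2.21), beside the B cell median of 2.19. Arrays of mixed cells cannot tell which cells gave a transcript. Single genes such as Cd2 and Bhlhe41 need not come from the cells their list is named for. The mast cell list passed camera with a median of 0.50 and 12 of 13 genes higher, among them Kit at 0.49 (adjusted p = 0.00579, and 0.712 with an estimated correlation). On it wild-type 5 stood at 0.66, above c-Jun-deleted 1 (0.54) and c-Jun-deleted 9 (0.48), and 0 of its genes lay above the wild-type range in both c-Jun-deleted arrays. On the T and NK cell list wild-type 11 stood at 1.53, above c-Jun-deleted 1 (0.14) and c-Jun-deleted 9 (0.66), and on the large macrophage list it stood at -0.73. Adjusted over the list alone 3, 0 and 0 genes of the large macrophage, T and NK cell and mast cell lists passed, and over all genes 0. The block medians were 0.64, 0.53 and 0.45, those within slide 2 were 1.32, 0.28 and 0.81, and those within slide 1 were -0.08, 1.03 and -0.15. Without wild-type 11 the large macrophage median was 0.14 (adjusted p = 0.126) and the T and NK cell median 1.16. Without wild-type 5 the large macrophage median was 1.23, the mast cell median 0.85 and the T and NK cell median -0.02 (adjusted p = 0.456). Without wild-type 14 the mast cell median was 0.25 (adjusted p = 0.115) and the T and NK cell median 0.06 (adjusted p = 0.352). With array weights the large macrophage median was 0.36, the T and NK cell median 0.91 and the mast cell median 0.22, whose call was lost (adjusted p = 0.154). The T and NK cell median was 0.66 without c-Jun-deleted 1, and its call was also lost without c-Jun-deleted 9 (0.14, adjusted p = 0.196), within slide 2 (adjusted p = 0.227) and under the 3 other scalings (adjusted p = 0.132, 0.159 and 0.157).

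Interferon-stimulated genes fell as a list, by a median of 0.63 with 35 of 37 genes lower, among them Ifi204 (-0.86), Ifitm3 (-0.87) and the RNA sensor gene Ifih1 (-0.76). Camera's adjusted p was 0.000648, and 0.773 with an estimated correlation. Oas1g was at -1.08, but well above background on only 1 of 2 c-Jun-deleted arrays and at -0.20 with normexp. Inflammatory cytokine and chemokine genes had a median of -0.76 with 25 of 30 lower, among them Il1rn, the interleukin 1 receptor antagonist (-1.49), Ccl4 (-1.41) and Cxcl16 (-0.62), while Csf1, a macrophage growth factor, was at 0.73. For this list camera's adjusted p was 0.0343, and 0.773 with an estimated correlation. AP-1 family genes had a median of -0.48 with 19 of 23 lower, and Maf (-0.84), Maff (-1.26), Jdp2 (-0.79), Junb (-0.48) and Jund (0.54) were among those outside the wild-type range. In that list 8 of 23 genes lay below the range and 2 above it. Over all genes tested the groups did not overlap for 33.5%. The AP-1 list had a camera adjusted p of 0.0343, and 0.712 with an estimated correlation. Matrix protease and remodelling genes were at -0.45 with 20 of 24 lower (camera adjusted p = 0.0191, and 0.712 with an estimated correlation), among them Mmp13 (-1.63), Hbegf (-1.51), Cd44 (-0.84) and Adam17 (-0.56). Apoptosis and survival genes were at -0.32 with 24 of 28 lower (camera adjusted p = 0.0116, and 0.712 with an estimated correlation), among them Cdkn1a, a cell cycle inhibitor (-1.19), and Birc3 (-0.59). Mesothelial and stromal markers were at -0.98 with 15 of 17 lower (camera adjusted p = 0.0153, and 0.712 with an estimated correlation), among them Wt1 (-1.47), Igfbp6 (-1.12), Sparc (-1.14) and Msln (-1.63); with normexp Wt1, Igfbp6 and Msln were at -0.75, -0.75 and -1.03. In these 6 lists 0 genes passed adjusted over the list alone or over all genes.

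In the order interferon-stimulated, cytokine, AP-1, matrix, apoptosis and mesothelial genes, the medians with the slide as a block were -0.61, -0.81, -0.49, -0.45, -0.34 and -0.82. Within slide 2 they were -1.15, -1.42, -0.57, -0.68, -0.49 and -1.05, and within slide 1 they were 0.09, 0.13, -0.08, -0.36, -0.12 and -0.44. Relative to the wild-type mean, cytokine genes stood at -0.22 on c-Jun-deleted 1 and at -1.19 on c-Jun-deleted 9, interferon-stimulated genes at -0.30 and -0.98, and matrix genes at -0.20 and -0.68. These are also the medians with the other c-Jun-deleted array left out. Wild-type 5 stood at -0.25 on the cytokine list and at -0.30 on the interferon-stimulated list, about where c-Jun-deleted 1 did. With median centring the medians of the AP-1, matrix and apoptosis lists were -0.27, -0.24 and -0.11, and with normexp the mesothelial one was -0.42, all still past camera. All 6 calls were lost with array weights (adjusted p from 0.0599 to 0.170), those of the AP-1 family (0.0530) and cytokines (0.0623) without the filter on dim probes, and each without some single array. Without c-Jun-deleted 9 the adjusted p was 0.258 for interferon-stimulated genes, 0.984 for cytokines, 0.346 for the AP-1 family, 0.258 for matrix genes and 0.115 for apoptosis genes. Without wild-type 11 the interferon-stimulated median was -0.27 (adjusted p = 0.258) and the mesothelial one -0.58 (0.111), and the adjusted p was 0.0698 for cytokines and 0.123 for apoptosis genes. Without wild-type 14 it was 0.209 for cytokines, 0.209 for the AP-1 family and 0.156 for matrix genes, and without c-Jun-deleted 1 it was 0.0617 for mesothelial markers.

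The other 11 lists did not pass camera, though 5 of them did under some alternative. The classical activation, cell cycle and osteoclast lists passed within slide 2, where c-Jun-deleted 9 alone stands against wild-type 11 and 14 and is assumed to vary like them. Their medians were -0.40, -0.72 and -0.61 there, against -0.06, 0.28 and 0.15 within slide 1. The cell cycle list also passed without wild-type 5 (0.00850), where its median was -0.61, against 0.04 without wild-type 11. The lipid list passed without the filter on dim probes (0.0147) and without c-Jun-deleted 9 (0.0481), and the phagocytosis list without wild-type 11 and c-Jun-deleted 1 together (0.0289), which was chosen after seeing the data. Lipid and cholesterol handling genes had a median of 0.01 (adjusted p = 0.149), with Scd1, a fatty acid desaturase (1.97), and Fabp4 (1.26) the 2 genes past the test adjusted over the list alone. Alternative activation genes were at -0.29 (0.492), with Mrc1 (-1.80), Folr2 (-1.91), Ccl17 (-1.52) and Irf4 (1.19). Classical activation genes were at -0.36 (0.195), with Nos2, the inducible nitric oxide synthase (-2.16), and Slamf1 (1.54, and 0.82 with normexp). Phagocytosis and lysosome genes were at -0.23 (0.403), with Fcgr4 (-2.45) and C1qb (-0.48), and osteoclast genes were at -0.39 (0.492), with Dcstamp (-1.68) and Tnfrsf11a, the RANK receptor (-0.74). Prostaglandin and leukotriene synthesis genes were at -0.04 (0.899), with Alox15 (1.66) and Tbxas1 (-0.62), and their median was 0.00997, 0.027 and 0.17 under normexp, quantile normalization and median centring. Cell cycle genes were at -0.32 (0.457), with Mki67 (-1.17) and Ccne1 (1.06), and neutrophil and eosinophil markers at -0.27 (0.748), with Il5ra (1.91) and Prtn3 (-1.18). Which cells gave the Il5ra signal cannot be told here. Small peritoneal macrophage, monocyte and dendritic markers had a median of -0.41 while camera's direction was up (0.909), with Napsa (1.83). Immediate early and stress genes were at -0.16 (0.689), with Nr4a2 (-0.65) and Dusp2 (0.91), and reference genes at -0.13 (0.457), with Pgk1 (-1.37), and both medians were positive with median centring, at 0.05 and 0.08. Adjusted over the list alone, 2 genes of the small macrophage list and 1 of the neutrophil list also passed, and 0 of the other 8. Fry, which does not set a list against other genes, passed 0 of all 23 lists for a common direction (smallest adjusted p = 0.104) and 6 for change in either direction, 3 of them among the 12 that passed camera.

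**Figure D2:**
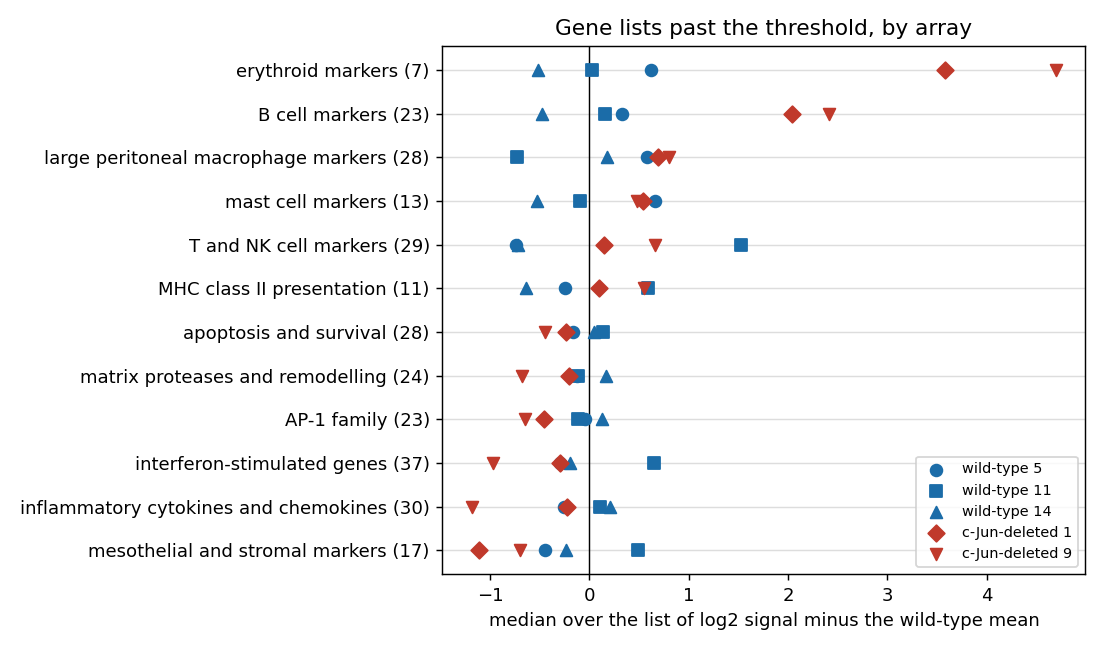
Median over the measured genes of each list of the log2 difference from the wild-type mean (x axis), with 1 marker per array, wild-type in blue and c-Jun-deleted in red. The B cell list stands at 2.04 and 2.41 in the c-Jun-deleted arrays and the erythroid list at 3.58 and 4.70, while wild-type 11 stands at 1.53 on the T and NK cell list.

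Genes near the modified alleles were compared because a mixed strain background can carry flanking chromosome along with an allele. The 68 measured genes within 10 Mb of Jun had a median of -0.19, with 47 lower (camera adjusted p = 0.368), and the median was 0.02 with median centring. The 75 within 10 Mb of Lyz2 had a median of -0.06 while camera's direction was up (adjusted p = 0.820), and the median was 0.15 with median centring. With the slide as a block the medians were -0.19 and -0.05, within slide 2 they were -0.14 and -0.12, and within slide 1 they were -0.20 and -0.0066. Fry for change in either direction gave an adjusted p of 0.000817 for the genes near Jun and 0.0450 for those near Lyz2, which does not set them against other genes. Camera on the size of limma's statistics regardless of sign, which does so, gave an adjusted p of 0.677 for both. Camera's adjusted p was 0.632 for both within 5 Mb, and 0.783 and 0.870 within 20 Mb.

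The authors' deposited table lists 1709 probes, 1042 higher and 667 lower in its c-Jun-deleted column, with no log2 difference smaller in size than 1.00. Differences in the authors' deposited table run from -4.43 to 4.87, and 21 genes of the B cell list are in it. Jun, Ptgs2, Arg1 and Lyz2 are not in the authors' deposited table. Of its probes, 38 were not well above background on any array used here.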

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

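Of the alternatives here, the joint removal of wild-type 11 and c-Jun-deleted 1 and the median spot signal under normexp were chosen after seeing the data. The count of 0 genes became 187 with median centring and 1 with array weights, and it was 1 at an adjusted p below 0.1 and 3395 at an unadjusted p below 0.05; it was 0 under each other alternative run. Jun kept its direction under all 19 alternatives. Ptgs2 was -0.44 and Lyz2 -4.24 within slide 1, and Arg1 was 0.11 with the number in the source names as replicate block and ran from -1.01 to 0.40 with single arrays left out. Of 90 other named genes, 87 kept their sign under every alternative; Nkx6-3 (-0.16 with normexp), Kit and Mrgprb1 did not, and 27 passed under some alternative. With normexp, 28 of the 90 kept their sign with a difference smaller by over 1.5 times. The 12 lists past camera, 6 higher and 6 lower, became 14 within slide 2 (5 higher, 9 lower, 11 of them among the 12), 9 without wild-type 11 and c-Jun-deleted 1 (4 higher, 5 lower), 6 with the replicate block (4 higher, 2 lower), 5 with array weights (5 higher, 0 lower), 0 with an estimated correlation and 7 to 12 with single arrays left out. Fry, which does not set a list against other genes, passed 0 lists in direction and 6 for change either way, 3 of them among the 12. Within slide 1 the median was 0.13 for cytokines, 0.087 for interferon-stimulated genes, -0.076 for large macrophage markers, -0.15 for mast cell markers and 1.69 for B cell markers. The B cell median of 2.19 had an adjusted p of 0.712 from camera with an estimated correlation and 0.104 from fry. Before adjustment over the lists these were 0.0539 and 0.00886. Prostaglandin genes were at 0.00997 with normexp, 0.027 with quantile normalization, 0.17 with median centring and 0.022 within slide 2. Median centring gave 0.052 for immediate early genes, 0.081 for reference genes, 0.022 near Jun and 0.15 near Lyz2, which was -0.0066 within slide 1. MHC class II genes were at -0.13 with the replicate block, lipid genes at -0.019 within slide 2, -0.021 with array weights and -0.18 without wild-type 11 and c-Jun-deleted 1, and small macrophage markers at 0.013 with outlying spots kept and 0.38 without those arrays. With single arrays left out, medians ran from -1.19 to -0.22 for cytokines, -0.98 to -0.27 for interferon-stimulated genes, -0.68 to -0.20 for matrix genes, -0.65 to -0.34 for the AP-1 family, -0.45 to -0.24 for apoptosis genes, -1.32 to -0.58 for mesothelial markers, 0.14 to 1.23 for large macrophage markers, 0.25 to 0.85 for mast cell markers, 1.97 to 2.41 for B cell markers, 3.58 to 4.70 for erythroid markers, -0.18 to 0.025 for prostaglandin genes, -0.13 to 1.15 for MHC class II genes, -0.14 to 0.13 for lipid genes, -0.36 to 0.19 for small macrophage markers, -0.61 to 0.035 for cell cycle genes, -0.021 to 1.16 for T and NK cell markers, -0.50 to -0.11 for alternative activation, -0.45 to -0.16 for classical activation, -0.54 to -0.12 for osteoclast genes, -0.36 to -0.074 for phagocytosis genes, -0.46 to -0.098 for neutrophil markers and -0.10 to 0.012 near Lyz2, and the differences from -1.88 to -0.72 for Ptgs2 and -4.42 to -0.36 for Lyz2. The cause was not tested. Leaving out a c-Jun-deleted array, or staying within slide 2, leaves 1 in that arm, which is assumed to vary like the others. Only numbers 1 and 2 of the source names are shared, and deviations of same-numbered arrays had r = -0.07 and 0.19 across genes, so they do not establish pairs. With that block 0 genes passed. Wild-type 14 alone has number 4, so the block leaves it out of the differences: Jun was at -0.75 with the block and without wild-type 14. The shared numbers 1 and 2 also coincide with slides 1 and 2. The authors' deposited table was not run as an alternative, since it gives only group means for part of the probes. Genes not well above background in a group have only bounds.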

Other observations

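Of the tests of explanations here, all but that of the second B cell list were chosen after the result was seen, though the other scalings they use were planned. Wild-type 11 differed from the other 4 arrays in sex-linked transcripts. The Y-linked genes Eif2s3y (3.27) and Ddx3y (1.35) were well above background on that array only, and Xist, the RNA of the inactive X chromosome, was by its brighter probe at -4.53 there against -0.04 to 0.74 on the others. Gata6, a transcription factor of large peritoneal macrophages chosen after its values were seen, was at -1.07 there and between 1.29 and 2.08 on the others. On the same array the list medians relative to the wild-type mean were 0.76 for cell cycle genes, 0.65 for interferon-stimulated genes, 0.59 for MHC class II genes and 0.77 for small peritoneal macrophage, monocyte and dendritic markers. The labels give male or female mice for the study without naming the sex of each sample. By these transcripts wild-type 11 was male and the other 4 arrays female, so sex was not balanced between the groups. Other differences of wild-type 11 cannot be told apart from sex.

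B cell markers were higher in both c-Jun-deleted arrays, with medians of 2.04 and 2.41. A lower share of macrophages would raise other cell types alike, and only the mesothelial and stromal list was tested for this. Its median was -0.98, at -1.11 and -0.70 on the c-Jun-deleted arrays, where the SD between wild-type arrays was 0.49. The medians were 0.34 for T and NK cell, 0.50 for mast cell, 4.14 for erythroid and -0.27 for neutrophil and eosinophil markers. These lists did not rise alike, but some rose, so a lower share as part of the difference is not excluded. Scaling alone is argued against by the lowest B cell median over the 3 other scalings, 2.08. A larger share of B cells left among the adherent cells is a candidate explanation: a second list of B cell genes, none in the fixed lists, had a median of 1.64, with 18 of 19 genes higher, and 22 of the 23 genes of the first list were above background on all wild-type arrays. Whether that share follows from the genotype, from the washing of the plates or from higher expression in the same cells stays open.

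Lyz2 was 21.4-fold below the wild-type mean in c-Jun-deleted 1 and 1.29-fold below it in c-Jun-deleted 9. Fewer macrophages in that sample would lower other macrophage genes too, but the phagocytosis and lysosome median there was -0.074, with an SD of 0.12 between wild-type arrays. Lyz1 was at 8.18 on c-Jun-deleted 1, above its wild-type mean of 7.59, with an outlying spot on 1 array kept. A defect of the Lyz2 spot cannot be told apart, since the array holds 1 Lyz2 spot, which has no outlier flag. The labels give both mice as heterozygous for LysM-Cre, which replaces Lyz2, whereas their source names give another Cre line, Mx. A different number of LysM-Cre copies in c-Jun-deleted 1 is a candidate explanation that goes against its label and was not tested. Which Cre line the mice carried was not tested either, also for c-Jun-deleted 9, where Lyz2 was only 1.29-fold lower. Jun was -0.62 and -0.66 from the wild-type mean on c-Jun-deleted 1 and c-Jun-deleted 9.

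Globin transcripts were higher in both c-Jun-deleted arrays, with differences between 4.14 and 4.87 for 3 genes, of which Hbb-bt was well above background on 1 wild-type array. With the main scaling, Hbb-b1 was at least 3.10-fold and Hbb-b2 at least 11.4-fold higher, since no wild-type array measured them well above background. With normexp their log2 differences were 0.81 and 1.69, so these bounds do not hold under that setting. Scaling alone is argued against by the lowest globin median over the 3 other scalings, 2.47. Red cells or their precursors are a candidate source that cannot be told apart here, because 0 of only 2 measured erythroid genes that are not globins were higher. Whether the difference follows from the genotype stays open.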
